A study of Homo sapiens and Mus musculus with 72 samples.

How the data were processed

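The series measured apparent binding affinities of transcription factors in native chromatin. FLAG-tagged factor was added to isolated nuclei at increasing concentrations, and bound DNA was read by anti-FLAG CUT&RUN or ChIP-seq with spike-in DNA from another organism, per the labels' protocols. The series has 72 libraries, of which 50 enter 8 titrations in 7 tables. The other 22 belong to a pair of cMYC-MAX CUT&RUN competition series and were not analysed here. In these, 11 libraries have 0 nM of the His-MYC competitor, so cMYC-MAX CUT&RUN without competitor was run in both series. Each group is 1 library, and each of the 8 titrations used here was run once.

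BWA 2.1, Picard 2.23.8, MACS2 2.2.7, SAMtools 1.9 and R 4.0.3, with the builds hg38, mm10 and dm6, are named in the submitters' processing notes, which give no role or order. The deposited relative enrichment is a fraction per site and library, scaled by the authors so that the highest library of a titration is 1 at each site. How the spike-in entered it is not given in the sources used here. The deposited Kd (nM) is the authors' fit per site. The deposited p-value is the two-sided Pearson p of the authors' fit correlation over the non-zero doses, as recomputed from the tables. The deposited strength over control is a score whose log scale is not stated, and it served within each table to match sites, to rank list members for naming and for the across-site rho with Kd. Read depth is unknown, since the tables hold fractions, so no counting interval is given. Tables were normalised separately, so enrichment levels were not tested across tables.

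The mouse SP1 table holds sites fitted in at least 1 of R1 mESC and R1 NPC. Where the fit p was 0.01 or above, its Kd was exactly the top dose of 500 nM, a placeholder rather than an affinity. The design, fixed before the data were examined, took the median over all sites of a table, so the value over all sites stands first and the value over fitted sites stands beside it. In the other tables no site held such a placeholder at the top dose.

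The planned refit was a 1-site saturation curve with free bottom and span, with Kd on a grid from 0.1 to 10000 nM. In 3 MCF-7 titrations its median sat at the upper end of that grid, so the planned error, the range of that median without each dose in turn, is void there. The other planned form had a free Hill exponent from 0.5 to 4. After the data had been seen, 2 more forms were added. The first was a 2-parameter Hill curve from 0 to 1 on the non-zero doses, with Kd from 1 to 2000 nM. It was kept because, of the forms tried, it came closest to the authors' Kd in the titrations with 6 or more doses, so its closeness is no independent check. In the 5-dose titrations it followed the authors' Kd poorly across sites. Spearman's rho was 0.18 for YY1 CUT&RUN, 0.26 for YY1 ChIP-seq and -0.03 for cMYC-MAX, against 0.95 to 0.998 in the longer titrations. The 2-parameter refits of single sites there show how that refit moves, not the error of the authors' Kd. The second was the half-maximum dose by interpolation at 0.5. The text uses 4 curve forms in all, and leave-one-dose-out ranges of the 2-parameter curve are given beside the planned ones because these were void in 3 titrations.

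On simulated titrations with 2000 sites each, made with the 2-parameter curve and the residual spread of each table, that fit gave Spearman correlations of true and fitted Kd of 0.73 for FOXA1, 0.81 for MCF-7 SP1, 0.74 for F121 YY1, 0.72 for mESC SP1 and 0.67 for NPC SP1. In the 5-dose designs they were 0.27 for YY1 CUT&RUN, 0.30 for YY1 ChIP-seq and 0.24 for cMYC-MAX, against 0.54, 0.57 and 0.54 for the 1-site fit and 0.52, 0.57 and 0.53 for the half-maximum dose. The 1-site fit missed the simulated FOXA1 Kd by a median of 2.46 on the log2 scale. Of 100 random sets of 30 FOXA1 sites, 3 fell outside the range of random sets with no change, and 62 did after a 1.1-fold change in Kd.

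Sites are not replicates, so no p-value was computed across sites. Groups of sites were described by the percentile of their median among 10000 random site sets of the same size, matched on strength in 10 bins. Sites were called outside the range below the 2.5th or above the 97.5th percentile. Dose trends were tested by two-sided exact permutation of Spearman's rho and Pearson's r against log10(dose + 1 nM), in the titrations with 6 or more libraries. The contrast of R1 mESC and NPC was tested by exchanging cell types within each dose. This gives 32 distinct exchanges with fits that use the 0 nM library. The 2-parameter fit does not use it, so there the exchanges come in mirror pairs of equal size. Overlap meant at least 1 bp. These p-values measure only the spread between dose libraries.

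Human sites were placed with a RefSeq gene table of GRCh38.p14 that gives gene ends but no strand. The planned promoter class was therefore replaced by sites whose centre lay within 1 kb of either end of a protein-coding or lncRNA gene. Gene names are those of the nearest protein-coding gene boundary, and exon, intron and UTR positions were not analysed here. No mouse annotation and no genome sequence were used, so mouse sites carry coordinates only. The planned motif contrast, the contrast of the 2 alleles in F121 cells and the 4 mouse gene lists were not analysed here. All genes of the 8 human lists were found in the reference. Older symbols were merged with the current symbol of the same gene, which left 72 genes from 78 symbols in oxidative phosphorylation and 30 from 31 in other MYC targets. NDUFA4 is an older symbol of both COXFA4 and a pseudogene. A first run took the pseudogene, and the final run takes the protein-coding gene, which changed 2 of the list medians slightly and no call. Coordinates are printed as the tables give them, and whether they count from 0 or 1 is not stated.

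Named sites follow a rule fixed before the data were examined, among sites with a passing fit and a Kd inside the range of the non-zero doses. It takes the 5 lowest and 5 highest Kd of each titration, up to 8 members of each list by strength, the 10 largest shifts of SP1 Kd in each direction, and sites at the genes of the factors. Alternatives concerned the curve form, site filters, left-out doses, overlap, the window around gene boundaries and matching. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.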

Results

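Purified FLAG-tagged transcription factors were titrated onto isolated nuclei, and the dose at which each genomic site filled was read as an apparent Kd. MCF-7, a human luminal breast cancer line, received FOXA1, SP1, YY1 and cMYC-MAX. F121 cells, a hybrid mouse embryonic stem cell (mESC) line, received YY1. R1 mESC and neural progenitor cells (NPC) derived from them received SP1. The titrations held 9 libraries for FOXA1, 8 for MCF-7 SP1, 7 for F121 YY1, 6 each for SP1 in mESC and NPC, and 5 each for the remaining MCF-7 titrations. The 0 nM ChIP-seq library served both YY1 and cMYC-MAX. Each dose was 1 library and none of these titrations has a repeat with the same method among them, so no value has a replicate SD. Read depth is unknown.

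The first question was at which doses added factor filled its sites. FOXA1, a pioneer factor of luminal cells, stayed at a median relative enrichment of 0.0826 at 50 nM, reached 0.477 at 250 nM, and had its maximum at 500 nM at 97.7% of 16964 sites. SP1, a factor of GC-rich promoters, had a median of 0.435 at 50 nM in MCF-7, and peaked at 250 nM at 72.3% of 2572 sites. YY1, a zinc finger factor of housekeeping promoters, was at 0.366 at 50 nM in F121 cells. In the MCF-7 titrations with 5 doses, the median at 100 nM was 0.131 for YY1 by CUT&RUN, 0.170 for YY1 by ChIP-seq and 0.0878 for cMYC-MAX, and every site had its maximum at 1000 nM. For FOXA1 and these 5-dose titrations no plateau was seen below the top dose. Filling there is relative to that dose, and saturation is not shown. Background without added factor was 0.0635 for FOXA1, 0.161 for MCF-7 SP1, 0.168 for F121 YY1, 0.0431 for YY1 CUT&RUN, 0.0532 for YY1 ChIP-seq, 0.0649 for cMYC-MAX, 0.000552 for mESC SP1 and 0.00258 for NPC SP1.

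**Figure D1:**
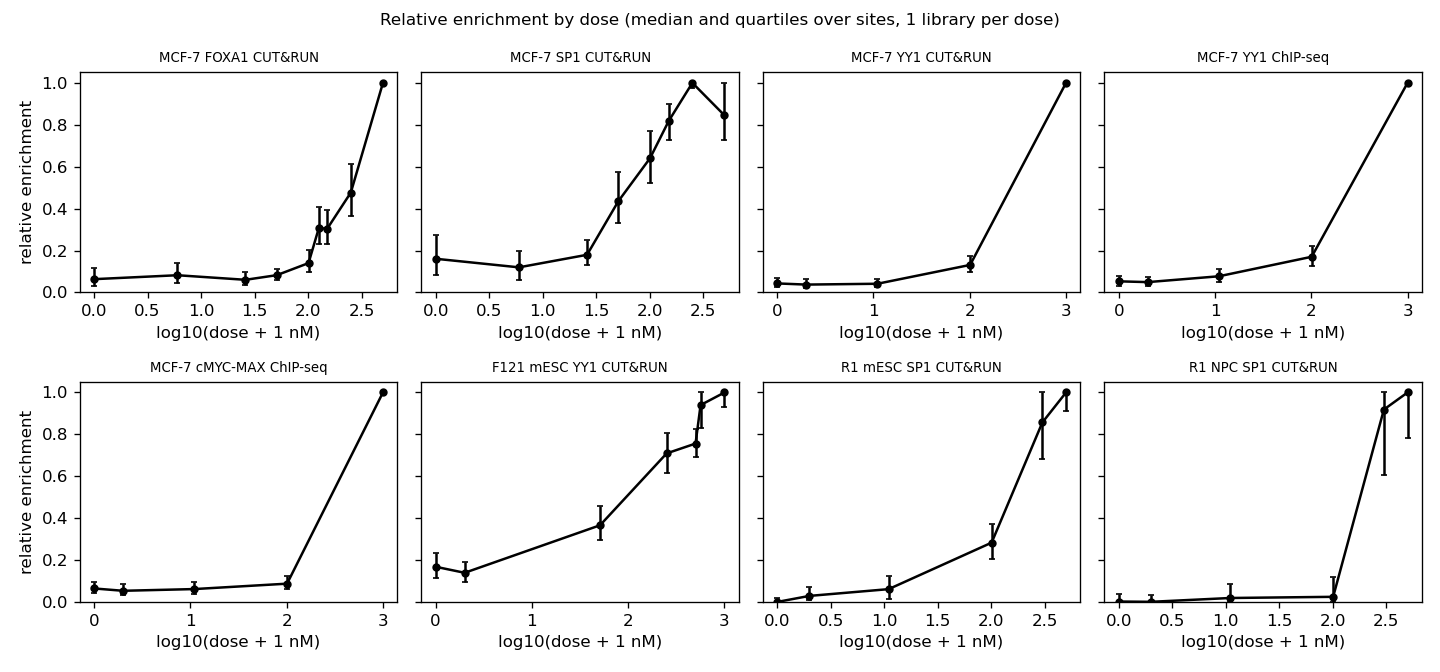
Median relative enrichment over sites (points) with quartiles (bars) against log10(dose + 1 nM), 1 library per point and 1 panel per titration. MCF-7 SP1 reached 0.435 at 50 nM while FOXA1 stood at 0.0826.

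The design tested dose trends by two-sided exact permutation, only with 6 or more libraries, but these tests are void as evidence of filling. In the human and F121 tables every site had a fit p under 0.01 and a fit r of at least 0.90, and the mouse SP1 table holds sites fitted in at least 1 cell type, so a rising median was largely fixed by the choice of sites, and scaling each site to its maximum fixes it further. The values describe only the shape over these sites. The 3 titrations with 5 libraries were not tested, and in each of them the median at 1 nM lay below that at 0 nM. Spearman's rho was 0.93 for FOXA1 (p = 0.00075), 0.95 for MCF-7 SP1 (p = 0.00114), 0.96 for F121 YY1 (p = 0.00278), 1 for mESC SP1 (p = 0.00278) and 0.94 for NPC SP1 (p = 0.0167). Over the 10 tests, the adjusted permutation p-values of rho ran from 0.00375 to 0.0226. Pearson's r was 0.69 (permutation p = 0.0435), 0.88 (p = 0.00198), 0.96 (p = 0.000397), 0.90 (p = 0.0181) and 0.81 (p = 0.0694) in the same order, with adjusted p-values of 0.0483, 0.00463, 0.00375, 0.0226 and 0.0694. Without the 2 doses farthest from the median, r was 0.89, 0.92, 0.97, 0.94 and 0.84. For FOXA1 the linear p was above 0.05 without the 5 nM library (permutation p = 0.108), the 25 nM library (p = 0.0610) or the 250 nM library (p = 0.0809).

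The median apparent Kd was lowest for SP1 in MCF-7, at 58.8 nM (quartiles 43.6 and 76.9), and, by the authors' Kd, highest among MCF-7 titrations for FOXA1, at 206 nM (175 and 237). The place of FOXA1 depends on the curve form: half-maximum doses were 255 nM for FOXA1, 266 nM for YY1 CUT&RUN and 283 nM for cMYC-MAX, and a free Hill exponent gave 579 nM for FOXA1, 325 nM for YY1 CUT&RUN, 1540 nM for cMYC-MAX and 2113 nM for YY1 ChIP-seq. F121 YY1 had 82.3 nM (59.7 and 112). In MCF-7, YY1 had 123 nM by CUT&RUN and 120 nM by ChIP-seq, and cMYC-MAX had 130 nM. SP1 had 152 nM in mESC and 275 nM in NPC over all sites, and 136 and 184 nM over the 6971 and 6831 sites with a fit. Refits with the 2-parameter Hill curve, without each dose in turn, put the median between 180 and 264 nM for FOXA1, 53.1 and 61.9 nM for MCF-7 SP1, 34.9 (without 50 nM) and 90.7 nM for F121 YY1, 74.9 (without 100 nM) and 138 nM for mESC SP1 and 143 and 227 nM for NPC SP1. In the 5-dose titrations the median was 49.2 nM for YY1 CUT&RUN and cMYC-MAX and 45.6 nM for YY1 ChIP-seq without the 100 nM library, and 2000 nM, the limit of the fit, without the 1000 nM library. The planned 1-site refit gave 94.4 nM for MCF-7 SP1 (70.8 to 237 without each dose in turn), 178 nM for F121 YY1 (158 to 205), 5309 nM for YY1 ChIP-seq (97.2 to 6879), 460 nM for mESC SP1 (158 to 10000) and 866 nM for NPC SP1 (115 to 10000). These planned ranges leave out the authors' medians for MCF-7 SP1, F121 YY1 and mESC SP1. It gave 10000 nM, its limit, for FOXA1, YY1 CUT&RUN and cMYC-MAX. Kd values of the 5-dose titrations lay between 101 and 163 nM. Every site there had a fit r of at least 0.99, so only sites close to the authors' curve are present. How far that choice of sites narrows the range was not tested.

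**Figure D2:**
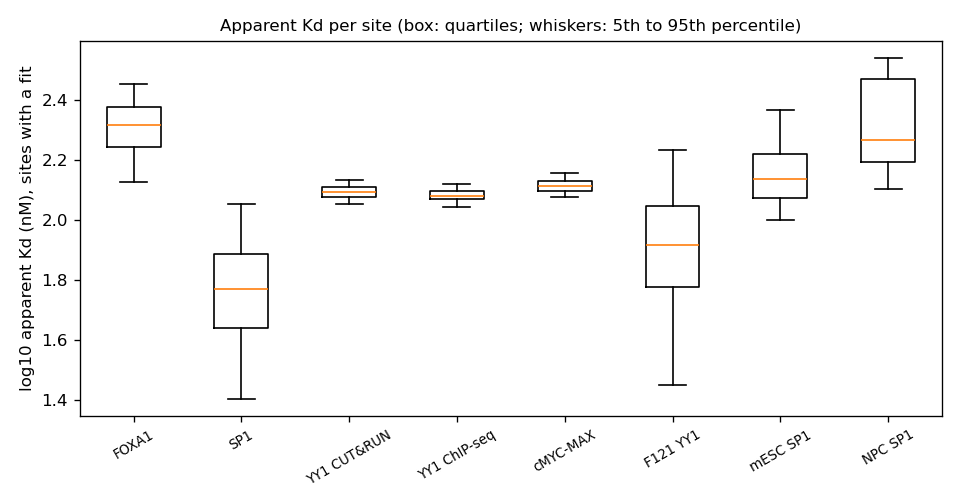
Log10 apparent Kd (nM) of sites with a fit, by titration; boxes are quartiles, the line is the median and whiskers run from the 5th to the 95th percentile. The 3 MCF-7 titrations with 5 doses have narrow boxes around 120 to 130 nM.

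In the authors' deposited table, the lowest FOXA1 Kd was 59.3 nM at chromosome 15, 51830322 to 51830680 (hg38), inside TMOD3, an actin-capping gene. The next were 66.3 nM near WNK2 and 67.6 nM near SERPINA12 in the same deposited table of the authors. The highest in the authors' deposited table were 311 nM at PTPN18, 310 nM near AP3M2 and 307 nM near WDR47. With the 2-parameter refit, the TMOD3 site had 33.6 nM without the 50 nM library and the WNK2 site 43.9 nM without 25 nM, and these and the SERPINA12 site stayed at 84.0 nM or below whichever dose was left out. The high sites depended on single doses. Without the 250 nM library the PTPN18 site had 195 nM and the sites near AP3M2 and WDR47 180 nM each, and without the 500 nM library these sites had 2000, 1853 and 1128 nM. For SP1 the authors' deposited table has its lowest Kd, 10.3 nM, inside PTGDS, the prostaglandin D2 synthase gene, at chromosome 9, 136978313 to 136978896, where the refit without the 5 nM library gave 1 nM, its limit. Its highest Kd, 210 nM in the authors' deposited table, lay inside the SP1 gene at chromosome 12, 53381587 to 53382170. Next in the authors' deposited table were 207 nM nearest SKIDA1, 202.4 and 202.3 nM nearest ASL, and 197 nM inside SP3, the gene of a related factor. Refits without 1 dose are not given for these high SP1 sites. At the FOXA1 gene the authors' deposited table lists FOXA1 Kd values from 190 to 230 nM over 4 sites. At the MYC gene the authors' deposited table gives 216 nM for FOXA1 and 128 nM for YY1 by CUT&RUN. At the MAX gene the authors' deposited table gives 129 nM for cMYC-MAX. Refits of the YY1 site at MYC gave 53.1 nM without 100 nM and 2000 nM without 1000 nM, and those of the cMYC-MAX site at MAX 51.1 and 2000 nM. In these 5-dose titrations the 2-parameter refit follows the authors' Kd poorly across sites (rho 0.18 for YY1 CUT&RUN and -0.03 for cMYC-MAX).

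YY1 in MCF-7 was measured by both methods at the same doses, which asks how far Kd depends on the follow-up assay. The 2 tables shared 3932 sites, 68.1% of the CUT&RUN sites, with medians of 123 and 120 nM. The median log2 ratio, ChIP-seq over CUT&RUN, was -0.03 (quartiles -0.08 and 0.03). Close medians say little about the assay here. Kd values of all 5-dose titrations lay between 101 and 163 nM, and cMYC-MAX, another factor, had a median of 130 nM. With the 1-site refit it was 0 over all doses, -1.25 without the 100 nM libraries and -0.29 without the 1000 nM libraries. Across sites, which are not independent replicates, Spearman's rho was 0.40 and Pearson's r of log10 Kd was 0.42. With the 2-parameter Hill refit rho was 0.096 and the ratio turned to 0.06. ATP5MC1, a subunit gene of ATP synthase, had 114 nM by CUT&RUN and 108 nM by ChIP-seq in the authors' deposited table. The authors' deposited table gives RPS11, a ribosomal protein gene, 108 and 105 nM, and 1 of the overlapping site pairs at FOXA1 117 and 120 nM. Refits without the 100 nM library gave 51.1 and 31.1 nM at ATP5MC1, 40.6 and 47.4 nM at RPS11 and 49.2 and 39.1 nM at the FOXA1 pair. Without the 1000 nM library they gave 264 and 161 nM, 174 and 133 nM, and 1717 and 2000 nM. Across sites, rho of the 2-parameter refit and the authors' Kd was only 0.18 by CUT&RUN and 0.26 by ChIP-seq.

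Factors were then compared at shared MCF-7 sites, with the doses differing between them. FOXA1 Kd exceeded YY1 CUT&RUN Kd at 98.7% of 4411 YY1 sites, with a median log2 ratio of 0.89. With the planned 1-site refit that ratio was 0, both fits being mostly at their limit, and the half-maximum medians over all sites of each titration stood the other way, at 255 and 266 nM. Over the 4691 FOXA1 sites that overlap a YY1 CUT&RUN site, the FOXA1 half-maximum median was 279 nM. A turned order at shared sites is therefore not shown. FOXA1 exceeded SP1 at 99.9% of 1904 SP1 sites, by 1.96. SP1 lay below YY1 at the median of 1696 shared sites, with a ratio of SP1 over YY1 of -1.03. With the 2-parameter curve that order needs the 100 nM library. Without it the refitted YY1 median over all its sites was 49.2 nM, against 53.1 to 61.9 nM for SP1 without any 1 dose. With the 1-site refit without 100 nM, SP1 stayed lower over all sites, at 97.2 nM against 10000 nM for YY1, the limit of the fit. By ChIP-seq, cMYC-MAX exceeded YY1 at 85.4% of 3134 sites, by 0.11. With a free Hill exponent the medians over all sites of each stood the other way, at 1540 and 2113 nM. Half-maximum medians over all sites (283 and 250 nM) and 2-parameter medians (161 and 155 nM) kept the order. So did the 1-site medians, 10000 nM, the limit of the fit, and 5309 nM. Across sites, rho of the Kd of both factors was -0.01 for FOXA1 and SP1, 0.02 for FOXA1 and YY1, 0.07 for SP1 and YY1, and -0.04 for cMYC-MAX and YY1. The last 3 pairs include 5-dose titrations, where simulated and refitted Kd correlated at 0.24 to 0.30 with the 2-parameter fit and 0.52 to 0.57 with the 1-site and half-maximum fits, so poor recovery lowers rho there by an amount that is not known for the authors' fit. For the last pair, which shares its 0 nM library, the 1-site refit, at its limit in 93.9% of cMYC-MAX sites, gave rho 0.0084, against 0.0070 on average over 100 simulations that moved the non-zero cMYC-MAX doses between sites, and covariances of 0.0098 and 0.0065. The 2-parameter refit gave rho 0.058, outside the simulated range of -0.030 to 0.036, whose mean was 0.0002. That form uses no 0 nM library. With the 1-site refit, part of any excess may come from the shared library.

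SP1 was set against itself in R1 mESC and NPC. Over all 9001 sites the median log2 ratio of Kd, NPC over mESC, was 0.51, with NPC higher at 68.7% of sites. At the 4801 sites fitted in both cell types the median of the per-site ratios was 0.49, with NPC higher at 83.6%. The median Kd over those sites was 135 nM in mESC and 173 nM in NPC. Across sites, rho of Kd between the cell types was -0.02 over all sites, placeholders included, and 0.13 at those fitted in both. The order of sites by Kd was thus hardly shared. A further 2170 sites were fitted only in mESC and 2030 only in NPC. The planned test did not set this difference apart from the spread between dose libraries: with the 1-site refit the ratio was 0.79, and 31 of 32 exchanges of cell types within doses gave one as large (two-sided exact permutation p = 0.969, smallest possible 0.0313). With the added 2-parameter refit the ratio was 0.44, and 18 of 32 exchanges were as large (exact permutation p = 0.562). That form uses no 0 nM library, so its exchanges come in mirror pairs of equal size. Its p could therefore not fall below 0.05, and it could not have set the cell types apart. The planned refit with a free Hill exponent gave 0.08. At 100 nM the median relative enrichment was 0.283 in mESC and 0.0250 in NPC, whereas at 300 nM it was 0.857 and 0.919. Without the 100 nM libraries the 1-site ratio was -0.12. The largest shift in the authors' deposited table was at chromosome 3, 54735186 to 54735636 (mm10), with 32.4 nM in mESC and 309 nM in NPC. The largest in the other direction in the authors' deposited table was at chromosome 8, 91801951 to 91802401, with 209 and 73.6 nM. The same NPC value of 73.6 nM also stands in the authors' deposited table at chromosome 6, 35539483 to 35539933. Refits without 1 dose are not given for these sites, so how far such values rest on single libraries is not known.

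**Figure D3:**
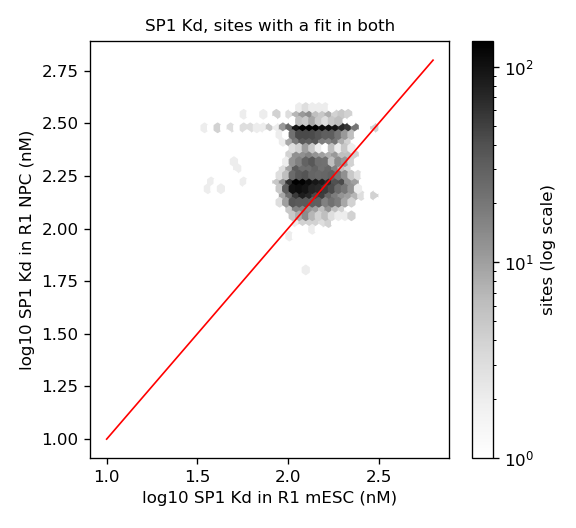
Log10 SP1 Kd (nM) in R1 NPC against R1 mESC at the 4801 sites fitted in both; grey shade is the number of sites on a log scale and the red line marks equal Kd. NPC was higher at 83.6% of the sites.

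Sites near gene boundaries made up 39.6% of FOXA1 sites, 77.2% of SP1 sites, 75.3% and 78.8% of YY1 sites by CUT&RUN and ChIP-seq, and 73.3% of cMYC-MAX sites. FOXA1 Kd was higher there, with a median of 226 nM against 193 nM elsewhere and a log2 ratio of 0.23, above the random range of 209 to 211 nM. YY1 medians were 123.1 against 124.5 nM by CUT&RUN and 120.02 against 120.81 nM by ChIP-seq, both below the random range, with log2 ratios of only -0.02 and -0.01. With the 1-site refit the YY1 CUT&RUN ratio was 0, at the limit of the fit, and the ChIP-seq ratio was -1.20 but turned to 0.62 without the 100 nM library and 1.20 without the 1000 nM library. SP1 had 59.0 against 58.3 nM, at the 75.8th percentile, and cMYC-MAX 130 against 129 nM, at the 87.7th. The FOXA1 contrast could not be seen with the 1-site refit, whose medians sat at the limit of the fit in both classes, giving a ratio of 0.

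Gene lists asked whether sites at functionally related genes differed in Kd. Of 39 combinations of list and MCF-7 titration with enough sites, 1 lay outside the range of random gene-boundary sites, and 1.95 were expected by chance. That one was SP1 at oxidative phosphorylation genes, with a median of 35.3 nM over 8 sites at 6 genes against 59.0 nM for all gene-boundary sites. In the authors' deposited table NDUFA11, a complex I subunit gene, had 22.4 nM, CYC1, the cytochrome c1 gene, 34.3 nM, and NDUFB11 92.0 nM. Without the 25 nM library the refit gave 18.9 nM at CYC1. Cytosolic ribosomal protein genes had a median FOXA1 Kd of 214 nM over 61 sites, at the 4.44th percentile. Mitochondrial ribosome genes had 206 nM, proteasome genes 211 nM, ribosome biogenesis genes and oxidative phosphorylation genes 222 nM each, luminal and oestrogen response genes and DNA replication genes 227 nM each, and other MYC targets 230 nM. For cMYC-MAX, ribosome biogenesis genes had 130 nM over 37 sites and other MYC targets 130 nM over 26 sites, at the 30.3rd and 15.8th percentiles. NPM1, the nucleophosmin gene, had 124 nM and CDK4, a cell cycle kinase gene, 126 nM for cMYC-MAX in the authors' deposited table. Refits gave 43.9 and 51.1 nM without 100 nM and 2000 and 1128 nM without 1000 nM. Across sites, rho of the 2-parameter refit and the authors' cMYC-MAX Kd was only -0.03. YY1 by CUT&RUN had 126 nM at proteasome genes, at the 96.8th percentile, and by ChIP-seq 119 nM, at the 36.0th.

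**Figure D4:**
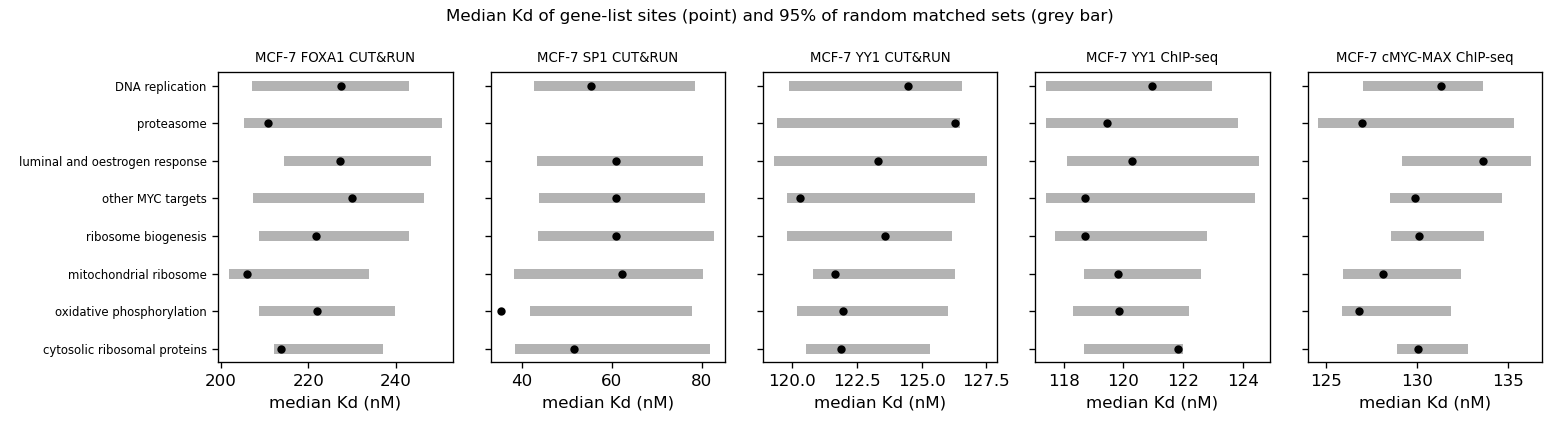
Median Kd (nM) of sites at 8 gene lists (points) in the MCF-7 titrations, with grey bars for 95% of 10000 random sets of gene-boundary sites matched on strength. Only SP1 at oxidative phosphorylation genes, 35.3 nM, lies outside its bar; a list with fewer than 5 sites has no point.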

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

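The contrast between gene-boundary sites and other sites went in opposite directions for different factors in MCF-7 by the authors' Kd. The log2 ratio of Kd was 0.227 for FOXA1, -0.0165 for YY1 by CUT&RUN and -0.00942 for YY1 by ChIP-seq. Each lay outside its random range, but the difference between factors was not tested, and both YY1 ratios are small beside the leave-one-dose-out ranges of their titrations. The opposite direction does not hold throughout: with the 1-site refit the ratio was 0 for FOXA1 and for YY1 CUT&RUN, both at the limit of the fit, and for YY1 ChIP-seq it turned to 0.62 without the 100 nM library and 1.20 without the 1000 nM library.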

How the results depend on the processing

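The 2-parameter Hill and half-maximum forms, and the filter on fit p in both cell types for SP1, were chosen after seeing the data; the other alternatives were planned. A median Kd counted as moved when it left the authors' value by more than 1 SD of the 2-parameter refits without 1 dose. In the 5-dose titrations that spread is so wide that even half-maximum doses of 266, 250 and 283 nM for YY1 CUT&RUN, YY1 ChIP-seq and cMYC-MAX did not count as moved, so no stability is shown there. Of the alternative values, 176 counted as unchanged, 86 moved, 20 became weaker, 2 stronger and 9 reversed. Some of the unchanged show nothing, because a filter left the value exactly as it was. The filter on the dose range did so for the median of every titration except SP1 in mESC and NPC. The filter on refit r2 did so for both YY1 titrations in MCF-7. The 1-site median without 0 nM stands under 2 planned settings, so each of the 8 titrations has a repeated row among the moved. Unchanged means the same side of a test's threshold without a change of sign, or a shift within 1 SD for values without a test. For the SP1 ratio of NPC over mESC it means only no change of sign, whatever the size. Unchanged also includes ratios of exactly 0, which have no direction. Examples are the 1-site ratios of FOXA1 over YY1 CUT&RUN (0 against 0.89) and of YY1 between the methods (0). Ratios of 0 show no stability. Where a median sits at 10000 nM, the limit of the grid sets that value, and why the fits ran to it was not tested. Elsewhere the cause was not tested either.

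With the 1-site refit the median Kd was 10000 nM for FOXA1, YY1 CUT&RUN and cMYC-MAX, with and without the 0 nM library and any other dose. It was 94.4 nM for MCF-7 SP1, 5309 nM for YY1 ChIP-seq, 178 nM for F121 YY1, 460 nM for mESC SP1 and 866 nM for NPC SP1. Without the 0 nM library these were 70.8, 5623, 168, 473 and 818 nM. Leaving out each dose in turn, they ran from 70.8 to 237 nM, 97.2 to 6879 nM, 158 to 205 nM, 158 to 10000 nM and 115 to 10000 nM. A free Hill exponent gave 579 nM for FOXA1, 325 nM for YY1 CUT&RUN, 70.8 nM for MCF-7 SP1, 2113 nM for YY1 ChIP-seq, 1540 nM for cMYC-MAX, 218 nM for F121 YY1 and 183 nM for NPC SP1. Half-maximum doses were 255 nM for FOXA1 and 178 nM for NPC SP1. For NPC SP1, sites inside the dose range gave 184 nM, because placeholders drop out, the stricter part by fit p 213 nM and the 2-parameter refit 187 nM.

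The linear dose trend of FOXA1 had r of 0.61 with log10(dose + 0.1 nM) (permutation p = 0.109), and from 0.67 to 0.78 without 1 library. Dose trends without 1 library were not run for the 6-library titrations, since the design asked for 6 or more libraries. The 2-parameter refit turned the YY1 ratio between methods to 0.055 and its rho to 0.096, and 1-site rho without 1 dose ran from 0.0042, without 100 nM, to 0.45. The 1-site ratio was -1.25 without 100 nM, -0.29 without 1000 nM and 0 without any other dose. With the 1-site refit the log2 ratio of SP1 over YY1 was -5.94 and that of FOXA1 over SP1 was 6.64, or 6.69 with FOXA1 on the doses shared with SP1. The NPC over mESC ratio stayed above 0 under the other curve forms and filters, down to 0.08. With the 1-site refit without 1 dose it ran from -0.12, without 100 nM, to 2.91, without 300 nM, and was 0 without 500 nM. The NPC median was at the limit of 10000 nM without 300 nM, and both medians were without 500 nM, so those ratios say little. At sites fitted in both, the 2-parameter refit without 1 dose gave 0.110, without 100 nM, to 0.441.

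At gene boundaries the 1-site ratio was 0 for FOXA1 and YY1 CUT&RUN in full and without any 1 dose, because both medians sat at the limit. For SP1 the ratio turned to -0.012 at 2.5 kb and -0.021 with the 1-site refit, and ran from -0.083 to 0.12 without 1 dose. For YY1 ChIP-seq it ran from -1.16 to 1.20 without 1 dose, turning to 0.62 without 100 nM. For cMYC-MAX it passed the range at 500 bp, with 0.0099, and without matching, with 0.0081, and its 1-site ratio was 5.48 without 1000 nM, inside the random range, and 0 without any other dose. SP1 ratios without 150 or 250 nM were both -0.042. Gene lists outside the range numbered 3 without matching, 2 with the 1-site refit, 2 at 500 bp and 4 with half-maximum doses, of 39 tested each time, against 1.95 by chance. The motif and allele contrasts were not run. Depth is unknown and sets no limit that can be given.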

Other observations

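FOXA1 sites that overlap a YY1 CUT&RUN site had a median Kd of 227 nM over 4691 sites, against 197 nM at the other 12273. In mouse ES cells, F121 YY1 and R1 mESC SP1 shared 3950 sites fitted for SP1, with medians of 86.4 nM for YY1 and 137 nM for SP1. Across-site rho of strength and Kd, over sites with a fit, was 0.36 for FOXA1, 0.39 for cMYC-MAX and 0.52 for F121 YY1, and -0.40, -0.14 and -0.26 for SP1 in MCF-7, mESC and NPC. YY1 in MCF-7 had -0.18 by CUT&RUN and -0.075 by ChIP-seq, so the sign did not follow the factor. The 5 lowest F121 YY1 values in the authors' deposited table were at 1 nM, the lowest non-zero dose. Whether that is a limit of the authors' fit is not known.

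The tests of the shared FOXA1 sites, the luminal genes and the mouse ES cell sites were set before their results were seen, and those of SP1 in NPC and of the 5-dose titrations only after. For the FOXA1 sites shared with YY1, peak strength alone did not account for the higher Kd over all sites, since the shared median lay at the 100th percentile of sets matched on strength. Gene boundaries alone did not either, since among distal sites the median was 216 nM over 1269 shared sites against 190 nM, again at the 100th percentile. At gene-boundary sites alone the picture differed: 230.0 nM against 220 nM, yet at the 0.01th percentile once matched on strength. So the pattern may hold only at distal sites, where 2-parameter refits without 1 dose gave log2 ratios from 0.06, without 250 nM, to 0.33, without 500 nM. No biological explanation was tested.

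The higher SP1 Kd in NPC cannot come from placeholder values alone, since the ratio was 0.491 at sites fitted in both cell types. Whether it rests on the 100 nM library cannot be told apart from a shift between the cells. Without that dose the ratio at those sites was -0.0415 with the 1-site refit and 0.110 with the 2-parameter refit, so the curve forms differ in direction and no second titration was used here to decide. A difference between cell types stays open and untested.

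In the 5-dose MCF-7 titrations, the level of Kd may be set by the curve form, since the half-maximum dose was 2.15 times the median Kd for YY1 CUT&RUN, 2.08 times for YY1 ChIP-seq and 2.18 times for cMYC-MAX. By the planned comparison of rho alone, whether the 100 nM value sets the Kd of a site cannot be told apart from an ordinary fit. Kd is fitted from these values, so its rho with the 100 nM value (-0.978, -0.958 and -0.979) is largely built in, and longer titrations also reached -0.943 (F121 YY1 at 50 nM), -0.933 (MCF-7 SP1 at 50 nM), -0.910 (FOXA1 at 250 nM), -0.860 (NPC SP1 at 300 nM) and -0.814 (mESC SP1 at 100 nM). Within the 5-dose titrations, however, the 1000 nM value was 1 at every site and could not order them. Rho of Kd with the 1 and 10 nM values was 0.087 and -0.0018 for YY1 CUT&RUN and 0.087 and 0.107 for YY1 ChIP-seq. For cMYC-MAX it was -0.40 and -0.34. So the order of sites by Kd there followed the 100 nM library more closely than any other. With no dose between 100 and 1000 nM, the true half-maximum dose cannot be placed within that gap.

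A hypothesis that FOXA1 binds more tightly near luminal genes was not borne out. Distal FOXA1 sites within 50 kb of the listed genes had a median of 205 nM over 101 sites against 193 nM, at the 86.0th percentile of matched distal sets. A second hypothesis was that Kd follows the site whatever the factor. In mouse ES cells rho between YY1 and SP1 Kd was 0.0166, below the level set beforehand. This cannot reject the hypothesis, since cell line and doses also differed and simulated Kd was recovered at only 0.74 and 0.72. Even SP1 against itself, in mESC and NPC, gave a rho of only 0.13 at sites fitted in both.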
